A study of Mus musculus with 2 samples.

How the data were processed

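The series holds polyA plus RNA-seq of mouse regulatory T cells. Per the labels, both libraries are technical replicates of 1 biological sample: primary cells of 1 adult male mouse aged 4 months, from a strain that combines a Foxp3 allele expressing CreERT2 with a Rosa26 YFP reporter. The RNA was fragmented by Covaris shearing. The labels describe the cells as having originated from a bone marrow haematopoietic cell and give no sort or gate. They are called library 1 and library 2 here, by their technical replicate number.

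Each library has 2 gene tables and 1 transcript table, all on the mm10 assembly according to the deposited readme texts. The larger gene table and the transcript table use the GENCODE M21 annotation and carry the column names that RSEM writes; the aligner and the software versions are not given in the sources used here. Their estimated counts (expected counts) are the authors' values per feature with no scaling. The deposited TPM values are scaled over all features of a table, as maximum likelihood and posterior mean estimates. The deposited FPKM values were scaled for length and depth by the authors. The transcript table also gives, per the file headers, the percent of a gene's TPM assigned to each transcript. The smaller gene table holds whole-number counts per gene without a header, deposited with the GENCODE M4 annotation and derived from an earlier alignment. Its counting tool, its strand setting and its treatment of reads that map to several places are not given in the sources used here.

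Gene symbols, positions and biotypes came from the GENCODE M21 annotation, joined by identifier. It matched 55536 genes and 141862 transcripts of the larger tables, and 22195 of the 22457 identifiers of the smaller tables after removal of version numbers. The remaining features of the larger tables, 96 spike-in sequences, 1 phiX174 sequence and 26248 features with numeric identifiers, were not used in the comparisons. For each gene, the share of its 50-base transcript windows that also occur in the transcripts of another gene on the same strand was computed as a measure of shared reads. The text calls these shared windows.

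All samples form 1 group, so no comparison between conditions exists. No paired analysis was possible because there is only 1 group. The gene lists and the tests of the comparisons were fixed before the data were examined; the closing section says which tests of explanations were not. A gene was called expressed at 1 TPM or more in both libraries. Values are given as the mean of the 2 libraries with their SD, which is technical. For 22 gene lists with 326 entries, of which 325 matched a symbol (Ahsp did not), the median of the members' mean TPM was placed among 10000 random lists of the same size drawn from all genes with a symbol. The lists cover regulatory T cell core and effector genes, resting T cell genes, T cell core genes, Foxp3 partner factors, effector cytokines, CD8 T and NK cell genes, B and plasma cell genes, myeloid genes, dendritic cell genes, red cell genes, megakaryocyte genes, progenitor genes, stroma genes, early response genes, heat shock genes, proliferation genes, interferon genes, housekeeping genes, mitochondrially encoded genes, histone genes and sex-linked genes.

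The libraries were compared gene by gene with an exact two-sided binomial test on rounded estimated counts, conditional on their sum, for genes with a summed count of 10 or more. The expected share came from library sizes scaled by TMM in edgeR, and p values were adjusted by the Benjamini-Hochberg method at 0.05. This test compares libraries, not conditions. One library on each side leaves no residual degrees of freedom for a model of dispersion per gene. The edgeR common dispersion over both libraries as 1 group gave the variation beyond counting error. Log2 ratios are library 2 over library 1 with a prior count of 0.5. The median log2 ratio of each list was placed among 10000 random lists matched on mean expression, each member drawn from genes within 50 ranks of it. The binomial test was tested on simulated data with counting error only, with 200 changed genes each time. At a 1.5-fold change it recovered 145 of them (72.5%) among 17548 genes tested, with 4 false calls. At 2-fold it recovered 188 among 17551 genes tested, with 7 false calls, and at 4-fold all 200 among 17532, with 12 false calls. The real libraries varied beyond counting error, so these numbers of false calls do not carry over to them.

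Transcript shares were taken for 15 genes, listing transcripts with 10% or more in either library. The 2 gene tables of each library were compared by the Spearman correlation across genes and by the number of genes that differ 4-fold after scaling to the total. Shares of counts have 95% exact Clopper-Pearson intervals.

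Named genes are the members of the lists, the 15 genes with the highest mean TPM, the 15 genes with transcript shares, and, among genes past the test's threshold with a mean TPM of 5 or more, the 10 with the largest log2 ratio in each direction. Other genes are said to be chosen after their values were seen. Some members of the lists are not reported here by name.

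The alternatives tried were thresholds of 0.5 and 5 TPM, FPKM, posterior mean TPM, TPM without mitochondrial genes, DESeq2 size factors, total count scaling, summed counts of 1 or 50, an added 1.5-fold difference, the smaller gene table, pseudocounts of 0.1 and 5, TPM with a pseudocount of 1, shares of TPM, a 2-fold difference between tables, and each library alone. Another 4 were added later: genes with under 5% shared windows, random lists from expressed protein-coding genes, random lists matched on mean expression and length, and genes with 100 or more counts.

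The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.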

Results

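The data are polyA plus RNA-seq of regulatory T cells, the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. They come from 1 adult male mouse and form 1 group of 2 technical libraries, so they describe levels in these cells and not a difference between conditions. Library 1 had 15821875 estimated counts on genes and library 2 had 16153671. Each value below is the mean of the 2 libraries, and ± is their SD (n = 2), which covers technical variation only. A count of 0 allows up to 3 counts, or 0.190 CPM in library 1 and 0.186 in library 2. Intervals and these floors cover counting error only.

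The sample expressed 13471 genes at 1 TPM or more in both libraries, of which 10251 were protein coding. Library 1 alone gave 14567 such genes and library 2 alone 14543. Actb, the cytoskeletal beta-actin gene (ENSMUSG00000029580.14, mm10 chromosome 5, 142903115 to 142906754, minus strand), had the highest level, 38017 ± 5224 TPM. Behind it stood CT010467.1, an rRNA gene, at 10906 ± 1716 TPM, and the ribosomal protein gene Rps19 at 9498 ± 534 TPM. Tmsb4x, which encodes the actin-binding peptide thymosin beta-4, reached 8696 ± 437 TPM. The level of Actb depended on a 241-base annotated transcript, Actb-209, which was given 64.9 ± 1.57% of the gene's TPM. The 10 most abundant genes held 9.04 ± 0.23% of counts and the 100 most abundant 25.6 ± 0.22%. Ribosomal protein genes, 77 in number, held 7.17 ± 0.33%. The mitochondrial genome held 3.51% of counts in library 1 (95% exact interval 3.50 to 3.52) and 4.15% in library 2 (4.14 to 4.16). Protein-coding genes held 90.0 ± 0.06%.

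What regulatory T cell genes the sample carried is the question that its label raises. All 26 core genes were expressed, with a median of 139.6 TPM, above every random list of the same size. Foxp3 itself (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245, plus strand) stood at 39.7 ± 4.91 TPM, from 858 and 777 counts. This level depends on Foxp3-207, a 1557-base transcript that was given 71.9 ± 4.24% of Foxp3 TPM and whose share is uncertain. Ikzf2, which encodes the transcription factor Helios (ENSMUSG00000025997.13, chromosome 1, 69531214 to 69687245, minus strand), stood at 464 ± 1.94 TPM. Of the Ikzf2 TPM, 59.4 ± 2.25% was given to a short retained-intron transcript, although a longer protein-coding transcript held more of the counts. The Ikzf2 level depends on this assignment. Izumo1r, the folate receptor 4 gene (ENSMUSG00000031933.17, chromosome 9, 14885814 to 14903949, minus strand), was the most abundant member of the list at 1008 ± 21.3 TPM. The TNF receptor family genes Tnfrsf4 (OX40) and Tnfrsf18 (GITR) reached 758 ± 47.5 and 541 ± 18.9 TPM. Il2ra, the alpha chain of the interleukin 2 receptor (ENSMUSG00000026770.5, chromosome 2, 11642807 to 11693193, plus strand), was at 266 ± 11.1 TPM and Il2rb, its beta chain, at 410 ± 23.2 TPM. Ctla4, an inhibitory receptor, was at 204 ± 1.10 TPM. Plagl1 was lowest at 2.19 ± 0.59 TPM, the only member under 5 TPM in either library.

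Effector regulatory T cell genes were mostly present at lower levels. Of 26 genes, 25 were expressed and 19 reached 5 TPM in both libraries; the median was 20.2 TPM. Batf, a transcription factor of activated T cells, stood at 121 ± 1.52 TPM, the chemokine receptor gene Cxcr3 at 114 ± 1.81 TPM and Gata3 at 106 ± 6.43 TPM. Klrg1, a receptor of terminally differentiated cells, was at 85.0 ± 3.38 TPM. Il10, an anti-inflammatory cytokine, was at 4.46 ± 0.11 TPM, Areg at 1.65 ± 0.18 TPM and Tbx21, which encodes T-bet, at 1.84 ± 0.28 TPM. Il12a had 0 counts in both libraries. The list lay above every random list from all genes, and at the 59.7 percentile among random lists of expressed protein-coding genes, an alternative added after the data were seen.

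Genes of resting, recirculating T cells were abundant as well. All 16 were expressed at 5 TPM or more, with a median of 133 TPM. Ccr7, a chemokine receptor that guides T cells to lymph nodes, was at 210 ± 6.51 TPM, Il7r at 205 ± 6.18 TPM and the transcription factor gene Tcf7 at 180 ± 3.85 TPM. Igfbp4 was lowest at 16.5 ± 1.51 TPM.

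T cell core genes had the highest median of the lineage lists, 332 TPM, with all 22 at 5 TPM or more. Cd3g, a signalling chain of the T cell receptor complex, was at 1178 ± 42.7 TPM and the kinase gene Lck at 1151 ± 0.47 TPM. Cd4 (ENSMUSG00000023274.14, chromosome 6, 124864692 to 124888221, minus strand) was at 213 ± 19.1 TPM, 107 times the level of Cd8a and 17.4 times that of Cd8b1. The constant gene Trac of the alpha chain, chosen after its values were seen, was at 2530.1 ± 81.9 TPM and Trdc of the delta chain at 2.96 ± 0.35 TPM.

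Factors reported to regulate or bind with Foxp3 were all expressed, 22 of 23 at 5 TPM or more, with a median of 29.8 TPM. Ets1 led at 624 ± 41.3 TPM, ahead of Elf1 at 115 ± 6.02 TPM and Ikzf1, which encodes Ikaros, at 106 ± 13.4 TPM. Runx1 stood at 29.6 ± 0.37 TPM and Runx3 at 8.99 ± 0.98 TPM. Stat5b and Stat5a, signal transducers of interleukin 2, stood at 30.7 ± 2.14 and 27.5 ± 0.91 TPM. Nr4a3 was lowest at 1.85 ± 0.34 TPM.

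Cytokines of conventional effector T cells were low. Of 14 genes, 4 were expressed, with a median of 0.307 TPM for the list. Cd40lg was at 22.4 ± 1.37 TPM, Tnf at 10.9 ± 0.58 TPM, Ifng at 4.15 ± 0.10 TPM and Il4 at 2.38 ± 0.15 TPM. Il2 was at 0.670 ± 0.11 TPM. Il17a, Il22, Il3 and Il9 had 0 counts in both libraries and were not detectable at this depth. The list lay at the 87.6 percentile among random lists, whose draw includes the many annotated genes with no counts, and at 0 among lists of expressed protein-coding genes, an alternative added after the data were seen.

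Markers of other lineages had medians under 3 TPM, with a few high members. Of 101 genes found in 8 lists, 30 were expressed and 16 reached 5 TPM in both libraries. Among random lists from all annotated genes, most of which were not expressed, the medians lay at the 99.1 percentile for dendritic cell, 98.6 for CD8 T and NK cell, 95.7 for B cell, 94.9 for red cell and 87.9 for myeloid genes, and at 73.3, 54.2 and 51.7 for progenitor, megakaryocyte and stroma genes. Among lists of expressed protein-coding genes, added after the data were seen, all 8 lay at 0.04 or lower. CD8 T and NK cell genes had 8 of 14 expressed and a median of 1.96 TPM: the chemokine gene Ccl5 was at 277 ± 12.8 TPM, while Cd8a was at 2.00 ± 0.25 TPM and Cd8b1 at 12.6 ± 2.51 TPM. B and plasma cell genes had 6 of 17 expressed and a median of 0.515 TPM, with 0.820 in library 1 alone and 0.34 in library 2 alone. Among them Ighm, the immunoglobulin mu constant gene (ENSMUSG00000076617.9, chromosome 12, 113418558 to 113422730, minus strand), stood at 1059 ± 28.4 TPM, while Igkc was at 31.8 ± 1.69 TPM and Cd79a at 1.24 ± 0.55 TPM. Dendritic cell and antigen presentation genes had 7 of 13 expressed and a median of 2.94 TPM: Cd74, the invariant chain of MHC class II (ENSMUSG00000024610.15, chromosome 18, 60803848 to 60812652, plus strand), was at 374 ± 14.5 TPM, H2-Aa at 9.87 ± 2.09 TPM and Itgax had 0 counts.

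Myeloid genes had 3 of 20 expressed, none at 5 TPM, and a median of 0.200 TPM, with 0.155 in library 1 alone and 0.080 in library 2 alone. Tyrobp was at 3.56 ± 1.71 TPM and S100a8 at 0.260 ± 0.11 TPM. Of 9 red cell genes found, 4 were expressed, with a median of 1.22 TPM. These 4 were globin genes with over 50% of their windows shared with other genes, led by Hba-a2 at 11.4 ± 2.31 TPM, so the level of each single gene is uncertain. None of 7 megakaryocyte genes and none of 10 progenitor genes was expressed, with medians of 0.040 and 0.160 TPM. Library 1 alone gave medians of 0.080 and 0.060 TPM, and library 2 alone gave 0 and 0.245 TPM. In library 2 alone 1 progenitor gene passed, Hlf, at a mean of 1.09 ± 1.12 TPM. Stroma genes had 2 of 11 expressed and a median of 0.030 TPM. These were Pecam1, an adhesion molecule that T cells also carry, at 86.2 ± 0.04 TPM, and the epithelial gene Epcam at 3.40 ± 0.97 TPM. The labels give no sort, so the share of other cells was not known.

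**Figure D1:**
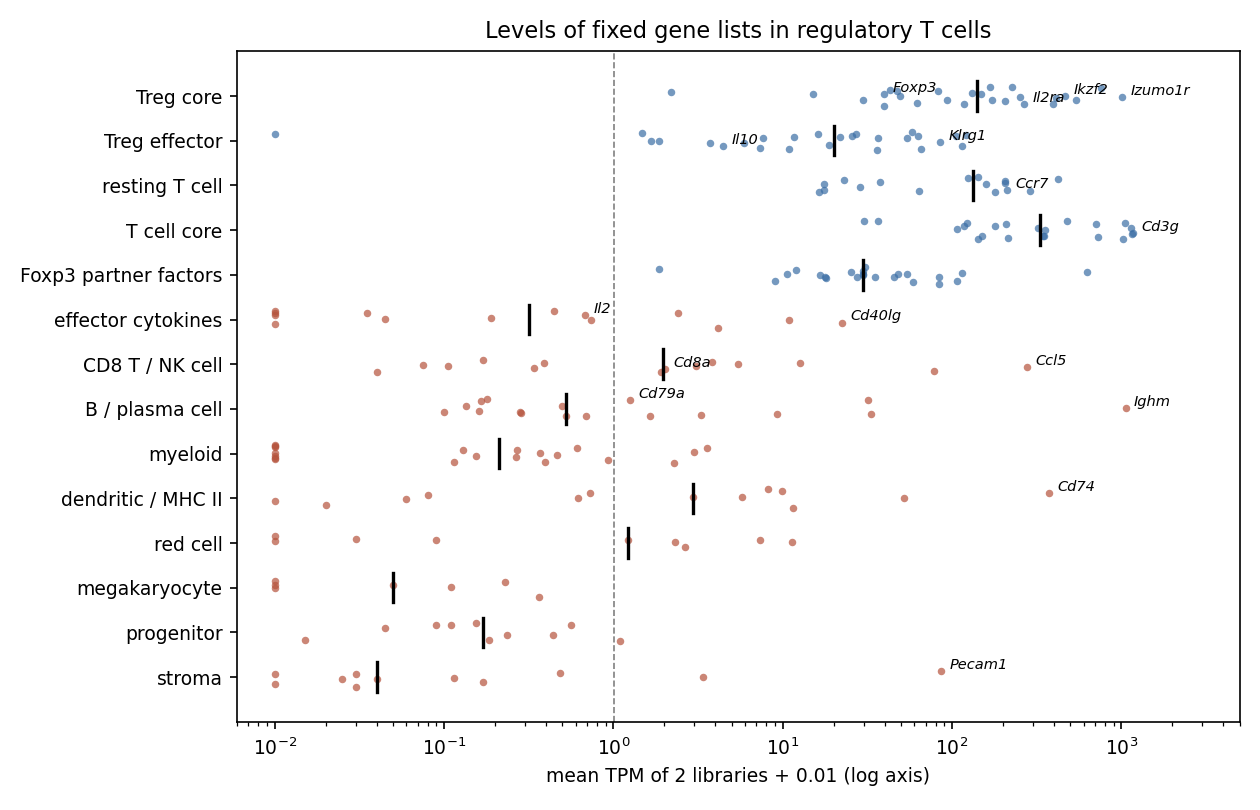
Each point is the mean TPM (log axis, 0.01 added) of a member of a gene list fixed before the data were examined, and each black bar is the list's median; the dashed line marks 1 TPM. The 5 lists of T cell genes in blue have medians from 20.2 to 332 TPM, and all lists in red have medians under 3 TPM, with Ighm, Cd74 and Ccl5 as high single members.

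Lists of cell state gave mixed levels. Early response genes, induced within minutes of stimulation, had 12 of 15 expressed and a median of 18.1 TPM, with Nfkbia at 502 ± 15.7 TPM and Fos at 8.44 ± 0.08 TPM. Heat shock genes had 7 of 8 expressed and a median of 78.3 TPM. The constitutive Hspa8 was at 2750.2 ± 8.20 TPM, while the stress-induced paralogs Hspa1a and Hspa1b, which share over 50% of their windows and are therefore uncertain singly, were at 1.09 ± 0.34 and 2.03 ± 1.05 TPM. Proliferation genes had 15 of 16 expressed and a median of 11.3 TPM, with Pcna at 106 ± 4.05 TPM and Mki67 at 5.66 ± 0.13 TPM. All 14 interferon genes were expressed, with a median of 36.2 TPM, among them Gbp2 at 113 ± 4.31 TPM and Irf7 at 90.6 ± 2.68 TPM. All 12 housekeeping genes were expressed, with a median of 726 TPM. The 13 mitochondrially encoded protein genes had a median of 1998 TPM, led by mt-Co3 at 7224 ± 604 TPM. Of 14 histone genes, whose mRNAs mostly lack poly(A), 9 were expressed, with a median of 3.81 TPM. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed, Eif2s3y at 95.2 ± 8.92 TPM, while Xist, which is transcribed from the inactive X chromosome, was at 0.210 ± 0.21 TPM; the median of these 5 sex-linked genes was 51.3 TPM.

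Transcript tables split each gene's TPM among its annotated transcripts. For all 15 genes examined the leading transcript was the same in both libraries, and the shares of the 31 transcripts listed differed by at most 7.71 points, with a median gap of 3.23 points. Foxp3-207, a 1557-base transcript annotated as subject to nonsense-mediated decay, was given 71.9 ± 4.24% of Foxp3 TPM, and the protein-coding Foxp3-206 was given 13.1 ± 2.76%. Of the annotated transcripts with the exon at 7585812 to 7585894, only Foxp3-207 ends short of the gene's 3′ end. Reads of that exon could be given to it for that reason, so its share is no measure of how much Foxp3 RNA is the decay form. The 4 transcripts that reach the gene's annotated 3′ end had 2.56% of the gene's count in library 1 and 4.15% in library 2. Ikzf2-205, a retained-intron transcript of 1905 bases, was given 59.4 ± 2.25% of Ikzf2 TPM, and the 9278-base protein-coding Ikzf2-201 was given 30.7 ± 1.08%. By estimated counts, which are not divided by length, the order was the reverse. Ikzf2-201 had 16692 counts in library 1 and 16755 in library 2, and Ikzf2-205 had 6173 and 6869. A single transcript held 99.0 ± 0.17% of Ctla4 TPM and 98.3 ± 0.17% of Tcf7 TPM. For Icos, Icos-202 held 50.8 ± 0.59% and Icos-201 held 49.2 ± 0.59%. Il2ra-201 held 76.5% of Il2ra TPM in library 1 and 73.5% in library 2, and Ptprc-203 held 35.5 ± 0.12% of Ptprc TPM. These shares are model estimates, and how many reads fit more than 1 transcript of a gene was not measured.

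**Figure D2:**
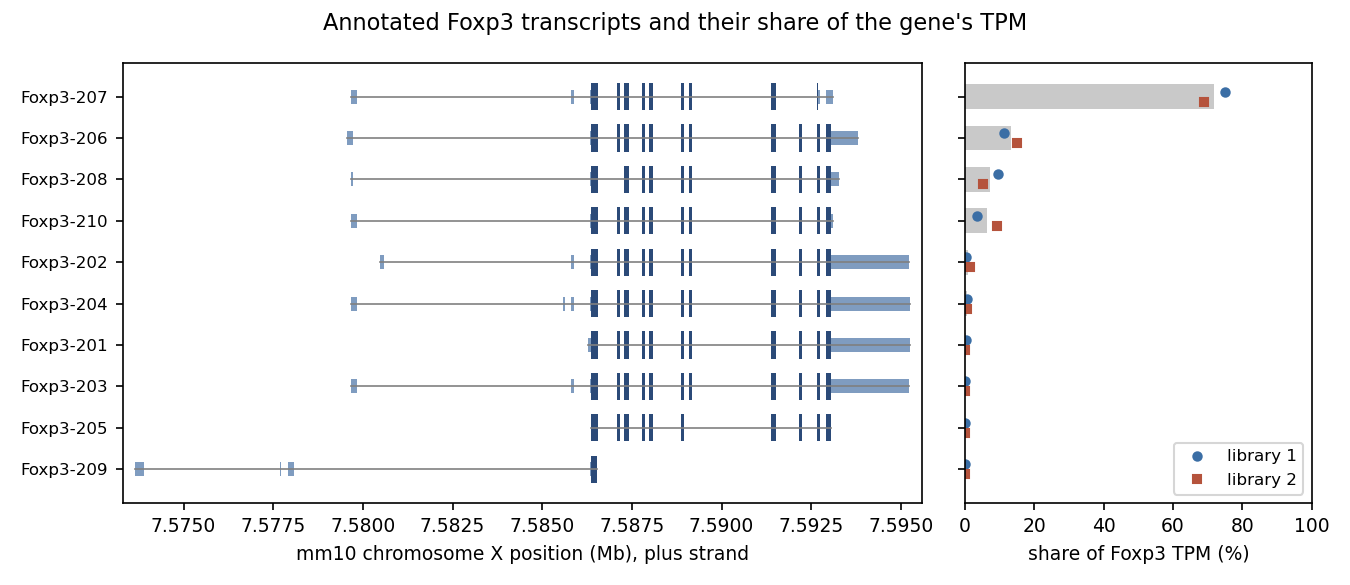
Annotated Foxp3 transcripts on mm10 chromosome X (light exons, dark coding parts; position in Mb) beside the percent of the gene's TPM given to each, as the mean of 2 libraries (bar) and each library (point). Foxp3-207 leads in both libraries with a mean of 71.9%. It is the only transcript with the exon at 7585812 to 7585894 that ends short of the annotated 3′ end, so its share is uncertain.

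How far 2 libraries of the same cells differ sets the precision of these levels. Across all genes the Pearson correlation of log2(TPM + 1) was 0.986 and the Spearman correlation 0.862, across genes that are not independent replicates. The median absolute log2 ratio was 0.15 for genes at 1 TPM or more in both libraries, and 0.01 over all genes, many of which had no counts. The exact binomial test called 4387 of 17458 genes different between the libraries, 2083 higher in library 2 and 2304 higher in library 1. Variation beyond counting error was 13% as a coefficient of variation. The test takes reads as independent molecules, and the mean chi-square per degree of freedom between libraries was 12.8, and the median 2.77, in genes with a summed count of 200 or more, so its p values are too small. Requiring also a 1.5-fold difference left 1537 genes, 762 higher in library 2 and 775 higher in library 1.

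Mitochondrially encoded genes stood out. Of 13 such genes, 12 differed and all 12 were higher in library 2, also 12 when adjusted over the list alone; their median log2 ratio was 0.21, above all matched random lists. Several of these genes, such as mt-Co2, share most of their windows with other annotated genes, so their single levels are uncertain. The whole mitochondrial genome moved the same way, from 3.51% of counts in library 1 to 4.15% in library 2. The 12 calls may thus be 1 shared shift, which random lists of unrelated genes do not allow for. Foxp3 partner factors had a median log2 ratio of -0.11, at the 0.970 percentile of matched lists; 9 of 23 differed, all higher in library 1, and also 9 adjusted over the list alone. Median log2 ratios fell with gene length, from 0.08 in the shortest eighth of genes to -0.09 in the longest, and the list lay inside the range, at the 15.3 percentile, among lists matched also on length, an alternative added after the data were seen. Examples are Ikzf1, with a log2 ratio of -0.24, and Stat3, with -0.20. Dendritic cell genes had a median of 0.25 at the 98.8 percentile, and 3 of 9 tested differed, also 3 adjusted over the list alone. Cd74 and Bst2 were higher in library 2 and Irf8 in library 1. Histone genes had a median of 0.27 at the 97.8 percentile, and at the 94.5 percentile, inside the range, among lists matched also on length. Of 11 histone genes 1 differed, and 4 when adjusted over the list alone; the 1 called, Hist1h2bc, ran against the median with a log2 ratio of -0.997.

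The other 17 lists compared lay inside the matched range. For scale, 4387 of all 17458 genes tested differed, and 3760 of the 12704 with a summed count of 50 or more. Each list is given with its count of differing genes adjusted over all genes tested first and that adjusted over the list alone second. Regulatory T cell core genes had 11 and 12 of 26 and effector genes 3 and 2 of 25. Resting T cell genes had 4 and 4 of 16, T cell core genes 14 and 16 of 22, and effector cytokines 0 and 0 of 7. CD8 T and NK cell genes had 3 and 3 of 10, B and plasma cell genes 2 and 2 of 11, myeloid genes 2 and 3 of 8, red cell genes 0 and 0 of 5, progenitor genes 1 and 4 of 5, and stroma genes 0 and 0 of 4. Early response genes had 5 and 6 of 14, heat shock genes 4 and 4 of 8, proliferation genes 8 and 8 of 16, interferon genes 5 and 5 of 14, housekeeping genes 7 and 7 of 12, and sex-linked genes 2 and 2 of 5. Megakaryocyte genes had under 3 members with enough counts and were not compared. Foxp3 had a log2 ratio of -0.17 with an adjusted p of 0.0621 in the exact binomial test.

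Dusp1, an early response phosphatase (ENSMUSG00000024190.7, chromosome 17, 26505590 to 26562128, minus strand), had 1018 counts in library 1 and 381 in library 2. Its log2 ratio was -1.45, with an adjusted p of 3.67e-67 in the exact binomial test, and the smaller gene tables gave 422 and 120 counts. AY036118, a lincRNA gene on chromosome 17 inside the rRNA gene CT010467.1, went from 105054 to 43761 counts; all of its windows are shared, so its level is uncertain. Of the 20 genes with the largest ratios at 5 TPM or more, 19 share at least 50% of their windows with other genes and are uncertain for that reason. Among all 2990 genes called at 5 TPM or more, 257 share as much, and 3391 of 13480 genes with under 5% shared windows differed. The 19 include the histone paralogs Hist1h2ah, with 83.9 counts in library 1 and 0 in library 2, and Hist1h2ai, with 0 and 138. The exception was Gm47248, an antisense gene with 0 counts in library 1 and 126 in library 2.

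Each library also has a smaller gene table, with 3746426 counts in library 1 and 3680387 in library 2, or 23.7% and 22.8% of the larger table. Cd4 had 1863 counts in the smaller table and 7796 in the larger one in library 1. Foxp3 had 563 and 858. Actb, in contrast, had 1981 counts in the smaller table against 395491 in the larger one. mt-Co1 had 1435 counts in both libraries of the smaller table, against 93355 and 109414 in the larger. Across 22195 shared genes the Spearman correlation of the tables was 0.938 in library 1 and 0.932 in library 2. After scaling, 1712 and 1883 genes differed 4-fold, of which 991 and 1068 were lower in the smaller table. Among genes with 100 or more counts in the larger table, a choice added after the data were seen, 662 were lower and 17 higher in library 1, and 690 lower and 16 higher in library 2.

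**Figure D3:**
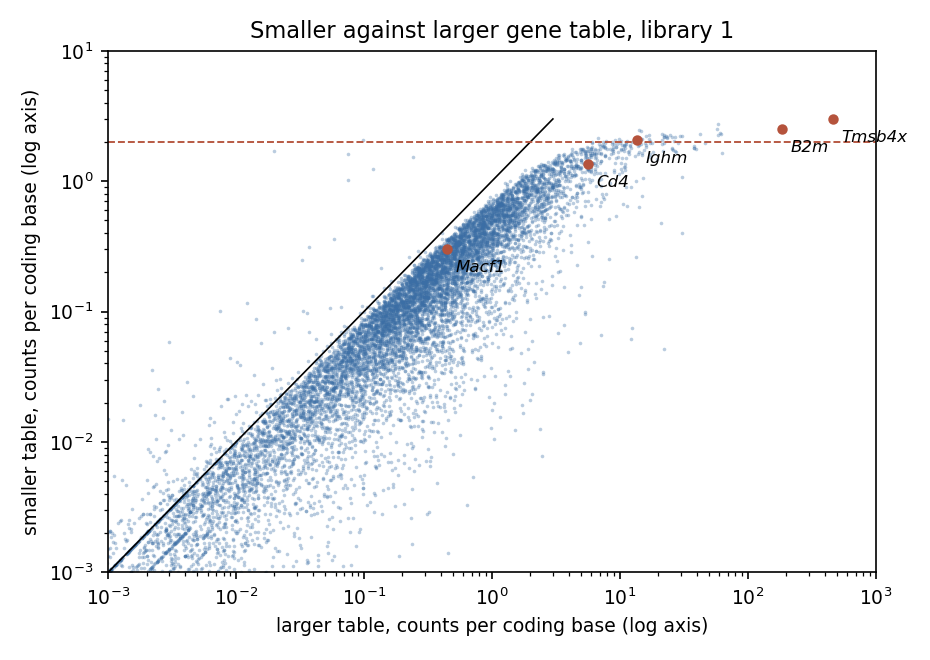
Counts per coding base in the smaller gene table against those in the larger gene table for library 1 (log axes), one point per gene with under 5% shared windows; the solid line marks equal counts and the dashed line 2 counts per coding base. Genes with many counts level off, up to 3.01 counts per coding base for Tmsb4x.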

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

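The larger gene tables hold counts for phiX174, a bacteriophage genome used as a control in sequencing runs, which no comparison used. It had 25263 estimated counts in library 1 and 24664 in library 2, or 0.159% and 0.152% of all counts, far above the 3 counts that a count of 0 allows. The 96 spike-in sequences of the same tables had 0 counts in both libraries. No explanation was tested.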

How the results depend on the processing

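The alternatives with under 5% shared windows, with random lists from expressed protein-coding genes or matched on length, and with 100 or more counts were chosen after seeing the data. Values stayed if they kept within the replicate SD (levels and shares), the SD of matched random lists (list ratios), 1.5 times (counts), 3 digits (correlations and dispersion) or the same side of the percentile limits. Of the values that answer a comparison 194 stayed and 32 did not; of the others 171 stayed, 54 moved and 3 reversed. The cause was not tested unless the setting's construction gives it. Part of the values that stayed could not have moved. With 2 libraries, the share in each library alone always lies within their SD, for gene classes and for transcripts. The Spearman correlation between libraries cannot change with the pseudocount. The numbers that stayed are thus no measure of robustness.

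As shares of TPM, which divides by length, the 10 and 100 most abundant genes held 10.3% and 33.4%, the mitochondrial genome 6.05% and ribosomal protein genes 15.7%. Genes that differ between libraries numbered 1537 with a 1.5-fold minimum and 1163 of 11149 tested in the smaller tables. They ranged from 3391 to 4389 under the other settings. The split between libraries was less even in the smaller tables, with 409 higher in library 2 and 754 in library 1. Among genes with under 5% shared windows it was 1469 and 1922. Variation beyond counting error was 11.5% at a summed count of 50 and 9.23% in the smaller tables. The smaller tables cover a different set of genes, and counts of abundant genes level off there. The lower value is therefore no measure of better agreement, and what lowered it was not tested. The Pearson correlation was 0.964 and 0.993 with pseudocounts of 0.1 and 5, and the median absolute log2 ratio was 0.0239 and 0.00541. For genes at 1 TPM or more, Pearson, Spearman and this ratio were 0.988, 0.982 and 0.15. With TPM and a pseudocount of 1, median log2 ratios were -0.0397 for regulatory T cell effector genes, -0.00568 for T cell core genes, -0.0181 for housekeeping genes, 0.17 for mitochondrially encoded genes and 0.0704 for histone genes. The sign also turned, within the SD of matched lists, for regulatory T cell core (-0.0157), progenitor (-0.0605), myeloid (0.00796), early response (-0.0266), heat shock (-0.0177) and sex-linked genes (-0.0259). Among lists matched also on length, Foxp3 partner factors and histone genes moved inside the range, to the 15.3 and 94.5 percentiles.

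At 5 TPM, a stricter threshold, expressed members numbered 2 effector cytokines, 4 CD8 T and NK cell genes, 0 myeloid, 2 red cell and 1 stroma gene, and 16 over 8 lists. Posterior mean TPM gave 1 megakaryocyte and 1 progenitor gene. Among random lists of expressed protein-coding genes, the percentile fell from above to below the range for CD8 T and NK cell genes (0), dendritic cell genes (0.04) and histone genes (0.03), since that draw leaves out unexpressed genes. It was also 0 for effector cytokines and the B cell, myeloid, red cell, megakaryocyte, progenitor and stroma lists, and 13.2 for proliferation genes. The tables' Spearman correlation was 0.752 for genes with 100 or more counts, of which 692.5 on average differed 4-fold; 14538.5 of all shared genes differed 2-fold.

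With each library alone, expressed genes ranged from 14543 to 14567, the shares of counts from 8.88% to 9.20%, 25.5% to 25.8%, 3.51% to 4.15% and 6.93% to 7.40% in the order above, progenitor genes from 0 to 1, members over 8 lists from 31 to 33, and table comparisons from 0.932 to 0.938 and 1712 to 1883. Depth limits genes near 0 counts, and the single biological sample leaves variation between mice unmeasured.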

Other observations

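The T cell receptor segments below, and the tests of lower depth, of coding bases, of the targeted allele, of reads shared by Foxp3 and of B cells, were chosen after the results were seen. Other tests of explanations were written before.

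Variable segments of the T cell receptor beta chain were broadly used, while the breadth of alpha segments is less certain. Of 108 annotated alpha segments, 97 were at 1 TPM or more in both libraries. The 5 most used held 15.8% and 16.9% of alpha segment counts. However, 67 of the 108 share at least 50% of their windows, so single alpha segments are uncertain. Some, such as Trav14d-1 and Trav14n-1, share all windows and were given equal counts, 130.1 in library 1 and 146.8 in library 2. Such splitting can raise the number at 1 TPM and lower the share of the 5 most used. Of 22 beta segments 21 were at 1 TPM or more, and the 5 most used held 40.7% and 42.0%. Trbv3 held 10.6 ± 0.07% of beta segment counts, Trbv13-2 held 8.73 ± 0.64% and Trbv19 held 7.58 ± 0.43% (SD, n = 2). Of 5 delta segments 2 were at 1 TPM or more. Gamma segments, 6 named Tcrg and 1 named Trgv, had 0 at 1 TPM or more in both libraries.

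In the smaller gene tables abundant genes had low counts: in genes with under 5% shared windows, the median ratio to the larger table was 0.495 and 0.481 where the larger table held under 0.3 counts per coding base and at least 50 counts, and 0.102 and 0.103 where it held 10 or more per coding base. Lower depth alone needs equal ratios, and the tables argue against it, since the ratio in dense genes was 0.210 of that in sparse genes, as the mean of the libraries. Keeping one read per start position and strand is a candidate explanation: in genes with 10 or more counts per coding base, the smaller table's count had a Spearman correlation of 0.550 with coding length, against 0.306 and 0.269 with the larger table's count, a gap that narrowed in genes with few shared windows to 0.765 against 0.601 and 0.763 against 0.594. Its strict form with coding bases alone allows about 2 counts per base, which 35 of 111 and 35 of 117 dense genes with few shared windows exceeded, while 0 exceeded 2 per exonic base. Counting of coding bases also stays open, as in sparse genes with at least 50 counts, a minimum set after a first look, the ratio had a Spearman correlation of 0.563 with the coding share; no biological explanation was tested.

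Few Foxp3 reads were assigned to transcripts that reach the annotated 3′ end, 2.56% and 4.15% against a median of 86.2% and 86.3% over expressed protein-coding genes. For loss of 3′ ends in all transcripts, the other 25 regulatory T cell core genes had a median share of 85.6%, with 3 of the 25 under 10% in both libraries. This share counts reads anywhere along a transcript whose annotation reaches the end. It does not measure coverage of the end itself, so the test cannot decide on such a loss. A targeted allele missing from the reference stays open. Foxp3 lay at the 6.33 percentile, between the bounds of 5 and 25 set for a decision. Those bounds were set after its low share was seen. A low rank also cannot tell this cause from others, so the test cannot decide. In a further comparison, not kept as a test, the Foxp3 ratio of the 2 gene tables was at the 92.6 and 91.3 percentiles of similar genes. No biological explanation was tested. Reads shared with other genes stay open only as part of the cause. The test was rewritten after each look, and the results of its 3 forms follow. Of all Foxp3 windows 14.7% were shared. Of distal windows 28.9% were shared with genes of the opposite strand, Ccdc22 and Gm36995. The count of those genes was 54.9% of the count expected of the distal part. It was 44.9% and 64.9% in the libraries, on either side of the bound of 50%. That count covers the whole of these genes, not the reads in the shared windows. On the same strand 0 of 1395 distal windows were shared, so this explanation needs reads of the opposite strand to be counted. Even then 403 of the 1395 were shared, and most distal windows lie in no other gene. The transcripts that hold these unshared windows still had only 2.56% and 4.15% of the Foxp3 count. These values argue against shared reads as the sole cause.

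Ighm was abundant while other B cell genes were low. For B cells as the source, the higher of Igkc and Cd79a reached 3.01% of the Ighm TPM. Cd79b, not part of that test, stood at 33.2 ± 0.10 TPM. Low levels of such genes are the pattern itself, so the test restates it and cannot decide on B cells. Shared reads of the same strand are argued against, with 0% of Ighm windows found in another gene on that strand. Windows of the opposite strand were not examined for Ighm. Rearranged heavy chain transcripts are argued against by heavy chain variable segments at 0.843% of the Ighm TPM, whereas alpha chain variable segments reached 65.9% and 67.8% of the Trac TPM. What gives the Ighm counts stays open.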
